A study of Rattus norvegicus with 6 samples.

How the data were processed

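The data are RNA sequencing counts from cultured neonatal rat ventricular myocytes, 3 libraries from cultures given DMSO and 3 from cultures given 10 µM compound 915, all for 72 h. Per the labels' protocols, ventricles of newborn pups were digested, fibroblasts were reduced by pre-plating and bromodeoxyuridine was present during plating, which limits the growth of other cells. Total RNA was extracted and sequenced on an Illumina instrument. Compound 332, which the design text also names, was not analysed here.

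Per the submitters' processing notes, the authors used STAR (version 2.5.1a), Subread featureCounts (version 1.4.6-p5) and the rat genome build Rnor_6.0. The strand setting and the treatment of reads that map to several places are not given in the sources used here, so overlapping genes and near-identical copies can share or lose reads. Echs1, for example, an abundant mitochondrial enzyme gene in heart, was counted at 0.997 CPM with DMSO and 1.66 CPM with 915 (named after its values were seen). The table of counts deposited by the authors holds 22641 rows, of which 993 repeat an Ensembl identifier with the same counts under another Entrez number. Repeats were dropped, which left 21648 genes, 26 of them without a symbol. The CPM table deposited by the authors equals those counts divided by 1 total per library. These totals, recovered from the ratio of the tables, were 42975767, 41528696 and 39513590 for DMSO libraries 1 to 3 and 38221508, 32709227 and 40652711 for 915 libraries 1 to 3. They exceed the sums of the count table (40010826, 38707933 and 36799845 for DMSO, 35796489, 30639244 and 38078137 for 915), so the table holds 93.1% to 93.7% of what was counted. A reference table of a later rat assembly, GRCr8, was used for gene names only, and no coordinates are given.

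Levels are given as deposited CPM, as mean ± SD over 3 libraries. At these depths 3 counts, the most that a count of 0 allows, correspond to 0.0698, 0.0722 and 0.0759 CPM in DMSO libraries 1 to 3 and 0.0785, 0.0917 and 0.0738 CPM in 915 libraries 1 to 3. This covers counting error only, since the reads carry no molecular identifiers. The libraries of a group differed by more than sampling noise (chi-square per degree of freedom 5.27 to 11.0 over genes), so no library is a copy of another.

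Fold changes, which are relative to the library totals scaled by TMM, and gene p-values came from edgeR 4.0.16 in R 4.3.3. The counts were filtered with filterByExpr, which kept 14253 genes, scaled by TMM and fitted with the quasi-likelihood model on group alone. The test was two-sided, with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05. The standard error of a log2 fold change is its size divided by the square root of the F statistic. The biological coefficient of variation was 6.84%. At an unadjusted p under 0.05, 7943 genes passed. The labels give both groups replicate numbers without saying that a number marks a shared litter or day, and the fit has no block for them. The share of counts from mitochondrially encoded protein genes was compared with an exact permutation test.

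Before the data were examined, 34 lists with 608 entries were fixed. There were 28 pathway lists and 6 lists of cell type markers, for fibroblasts, smooth muscle and pericytes, endothelium, macrophages and leukocytes, erythroid cells and neural crest. Of the entries, 558 matched a gene of the table, 1 of them through the reference. Each list was tested with camera of limma 3.58.1 on log2 CPM values with a prior count of 2 and a preset inter-gene correlation of 0.01, with Benjamini-Hochberg adjustment over the lists. It was tested again with a correlation estimated from the 6 libraries. This form of camera also takes its degrees of freedom from the libraries and not from the genes, which by itself raises its p-values. Fry was run as well. It asks whether the genes of a list move on balance in 1 direction and does not compare them with other genes. Of the lists 31 passed in fry. Members called higher or lower passed the edgeR threshold over all genes, and the counts adjusted over the list alone use only the members' own p-values.

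The genes named in the text follow a rule fixed at the same time. It took 10 genes regardless of their values (Esrra, Esrrb, Esrrg, Ppargc1a, Pdk4, Cpt1b, Myh6, Myh7, Nppa and Nppb), the 8 highest and 8 lowest log2 fold changes among genes with an adjusted p under 0.05, a mean of at least 5 CPM, all 915 libraries on the same side of all DMSO libraries and a symbol that is not a placeholder, and up to 3 members of each list with the smallest p under the threshold. Some genes that meet this rule are not reported here. Other genes are said in the text to have been chosen after their values were seen. Mt-cox3 is such a gene, and it was counted in the mitochondrial share but not in the list.

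The procedure was tested on simulated counts with the means and library sizes of this comparison. Over 14116 genes, 63 of 99 genes changed by 0.5 on the log2 scale (63.6%) and 87 of 99 changed by 1 (87.9%) were recovered, and 9 of 159 calls (5.66%) were false. Only this small set was changed, in random directions, whereas 49.8% of the real genes were called and large changes were mostly decreases. The shares recovered and false may therefore differ in the real comparison. In a simulation of the lists over 14253 genes, a fatty acid oxidation list shifted by 0.5 was called and 0 of 32 lists without shifted genes were. The simulated genes varied independently of each other, so this does not show how often camera calls lists of correlated genes by error. The alternatives tried were size factors of DESeq2 (version 1.42.0) and upper-quartile scaling, DESeq2, limma-voom and limma-trend on log2 of deposited CPM plus 1 or 0.5 as other tests, other filters, a replicate block, removal of mitochondrially encoded genes and leaving out each library in turn. After the data were seen, scaling by library totals without TMM and the authors' totals with TMM were added.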

Results

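RNA was sequenced from neonatal rat ventricular myocytes, heart muscle cells isolated from newborn pups and kept in culture. Cultures received either DMSO, the solvent, or 10 µM of compound 915 for 72 h, and each group held 3 libraries. The submitters describe 915 as an agonist of the estrogen-related receptors (ERRs), nuclear receptors known to drive genes of mitochondrial energy metabolism. The deposited gene table held 36799845 to 40010826 counts per DMSO library and 30639244 to 38078137 per 915 library, so that 3 counts corresponded to between 0.0698 and 0.0917 CPM (counts scaled to a common library total). The labels call the libraries biological replicates but do not say whether they came from separate cell isolations, so the p-values measure the spread between these libraries, which may be partly technical.

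The comparison asked which genes change in cardiac myocytes exposed to an ERR agonist, with fatty acid metabolism and mitochondrial function as the stated interest of the study. With 915, 68 of 70 measured nuclear genes of the respiratory chain and ATP synthase were higher and 0 were lower, and 18 of 19 genes of fatty acid oxidation were higher. All 21 measured cell cycle genes and all 17 measured genes of cholesterol synthesis and uptake were lower. Transcripts of the insulin-responsive glucose transporter Slc2a4 were 6.05-fold higher (11.1 ± 0.117 CPM with DMSO and 64.9 ± 3.51 with 915, mean ± SD, n = 3 each), and those of the mitotic kinase Cdk1 were 3.42-fold lower (43.3 ± 2.73 and 12.2 ± 1.06 CPM). Of 20 measured genes of TGF-beta response and extracellular matrix 17 were lower, while chemokine genes such as Cxcl1 and Ccl2 were 8.98-fold and 4.02-fold higher.

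Across the transcriptome, 7096 of 14253 tested genes (49.8%) passed an adjusted p of 0.05 in edgeR's quasi-likelihood test, 3460 higher and 3636 lower with 915. Changes of at least 2-fold were more often decreases: 252 genes were higher and 984 lower by that margin. On log2 CPM values the main axis of variation, 70.6% of the variance, separated all 915 libraries from all DMSO libraries. Correlations across genes were 0.993 to 0.994 within the DMSO group, 0.991 to 0.992 within the 915 group and 0.970 to 0.975 between groups. Of the 34 gene lists, 26 were shifted by camera's competitive test with a preset inter-gene correlation, 18 upwards and 8 downwards. With the correlation estimated from these 6 libraries, 1 list kept its call, the cell cycle list. Counts of members adjusted over the list alone were the same as those adjusted over all genes unless stated.

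**Figure D1:**
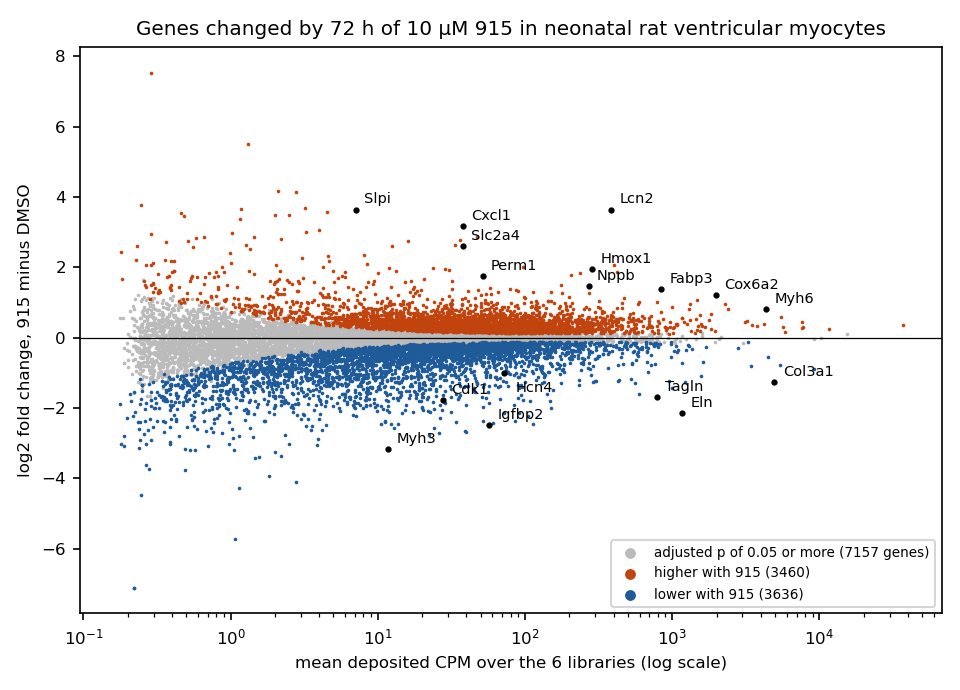
Log2 fold change (915 minus DMSO) of the 14253 tested genes against their mean deposited CPM over the 6 libraries, on a log axis. Coloured points are the 3460 higher and 3636 lower genes at an edgeR adjusted p under 0.05, grey points did not pass, and black points mark genes named in the text, among them Lcn2, Slc2a4, Eln and Myh3.

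The receptors addressed by the compound were themselves expressed at higher levels. Esrra (ENSRNOG00000021139), which encodes ERRα, went from 92.8 ± 6.93 to 135 ± 4.78 CPM, a log2 fold change of 0.59 ± 0.0610 (SE; edgeR adjusted p = 2.04e-06). Esrrg (ENSRNOG00000002593), which encodes ERRγ, rose from 38 ± 1.69 to 72.0 ± 3.97 CPM (log2 fold change 0.97 ± 0.0619, edgeR adjusted p = 1.44e-08). Esrrb (ENSRNOG00000010259), for ERRβ, was scarce and rose from 1.31 ± 0.474 to 3.28 ± 0.208 CPM (1.37 ± 0.246, edgeR adjusted p = 3.46e-04). The coactivator gene Ppargc1a (ENSRNOG00000004473) did not pass the test, at 30.4 ± 2.07 CPM with DMSO and 30.9 ± 2.09 with 915 (0.07 ± 0.0719, edgeR adjusted p = 0.448). Its relative Ppargc1b was 1.72-fold higher. Perm1 (ENSRNOG00000020244), a muscle regulator that acts with PGC-1 and ERRs, rose 3.33-fold from 24.5 ± 2.01 to 78.9 ± 2.79 CPM (1.74 ± 0.0683, edgeR adjusted p = 1.25e-10). Of the 9 measured ERR receptors and coactivators 7 were higher and 0 lower (camera adjusted p = 1.08e-03; adjusted p = 0.233 with an estimated correlation). Of the 12 measured established ERR target genes 11 were higher and 0 lower, with a median log2 fold change of 0.58 (camera adjusted p = 3.03e-06; adjusted p = 0.233 with an estimated correlation). Among these targets Cpt1b, Vegfa and Pdk4, which encode the muscle carnitine palmitoyltransferase, an angiogenic growth factor and a kinase that restrains pyruvate oxidation, rose 2.40-fold, 1.82-fold and 1.59-fold. In the same libraries the medians of the fibroblast, smooth muscle and macrophage marker lists were −0.55, −0.24 and −0.77.

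Genes of fatty acid handling rose together. The fatty acid oxidation list had 18 of 19 members higher and 0 lower, with a median log2 fold change of 0.57 (camera adjusted p = 8.45e-08; adjusted p = 0.255 with an estimated correlation). Cpt1b (ENSRNOG00000010438), the entry step of long-chain fatty acids into mitochondria, went from 163 ± 14.7 to 378 ± 8.37 CPM (log2 fold change 1.26 ± 0.0627, edgeR adjusted p = 1.14e-09). Cpt2 rose 1.81-fold and Hadhb, a subunit of the mitochondrial trifunctional protein, 1.63-fold. Of 19 measured genes of fatty acid uptake, storage and PPAR response, 15 were higher and 2 lower (median 0.67, camera adjusted p = 1.16e-05; adjusted p = 0.263 with an estimated correlation). The heart fatty acid binding protein gene Fabp3 and the fatty acid transporter gene Cd36 rose 2.61-fold and 2.55-fold. Without 915 library 1 or 2 the lower members numbered 1. Fibroblast and macrophage markers were lower in the same libraries, with list medians of −0.55 and −0.77.

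The respiratory chain and ATP synthase list had a median log2 fold change of 0.44, and 2 of its 70 members did not pass (camera adjusted p = 2.03e-16; adjusted p = 0.263 with an estimated correlation). Its clearest members were Cox6a2, the muscle form of a cytochrome c oxidase subunit, at 2.31-fold (1217 ± 74.7 and 2719 ± 143 CPM), the complex I gene Ndufb5 at 1.63-fold and the ATP synthase gene Atp5c1 at 1.5-fold. Of 16 measured genes of the tricarboxylic acid cycle, 15 were higher and 0 lower, by a smaller median of 0.29 (camera adjusted p = 1.63e-05; adjusted p = 0.261 with an estimated correlation). The cycle enzymes Idh3B and Idh2 each rose 1.4-fold. Alongside these nuclear genes, the fibroblast, smooth muscle and macrophage lists had medians of −0.55, −0.24 and −0.77. Transcripts of mitochondrial DNA moved less evenly: 8 of 12 listed protein genes were higher and 1 was lower, a decrease of Mt-atp8 that no longer passed without DMSO library 1 or 3 or without 915 library 1 or 3 (camera adjusted p = 0.0183; adjusted p = 0.462 with an estimated correlation). Mt-nd5, Mt-nd4 and Mt-co1 rose 1.51-fold, 1.36-fold and 1.28-fold, while Mt-cox3, which the table carries under a symbol outside the list, had a log2 fold change of 0.11 (edgeR adjusted p = 0.0874). Together the mitochondrially encoded protein genes took 11.0% ± 0.140 of the authors' library totals with DMSO and 12.6% ± 0.602 with 915 (SD, n = 3 each). The difference of 1.6 percentage points had an exact two-sided permutation p of 0.1, the smallest that 3 against 3 libraries allow. Mitochondrial dynamics and DNA maintenance genes were higher in 9 of 15 cases and lower in 0, among them the fusion genes Mfn1 and Opa1 and the mitochondrial RNA polymerase gene Polrmt (1.39-fold, 1.25-fold and 1.56-fold; camera adjusted p = 3.46e-03, adjusted p = 0.202 with an estimated correlation).

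**Figure D2:**
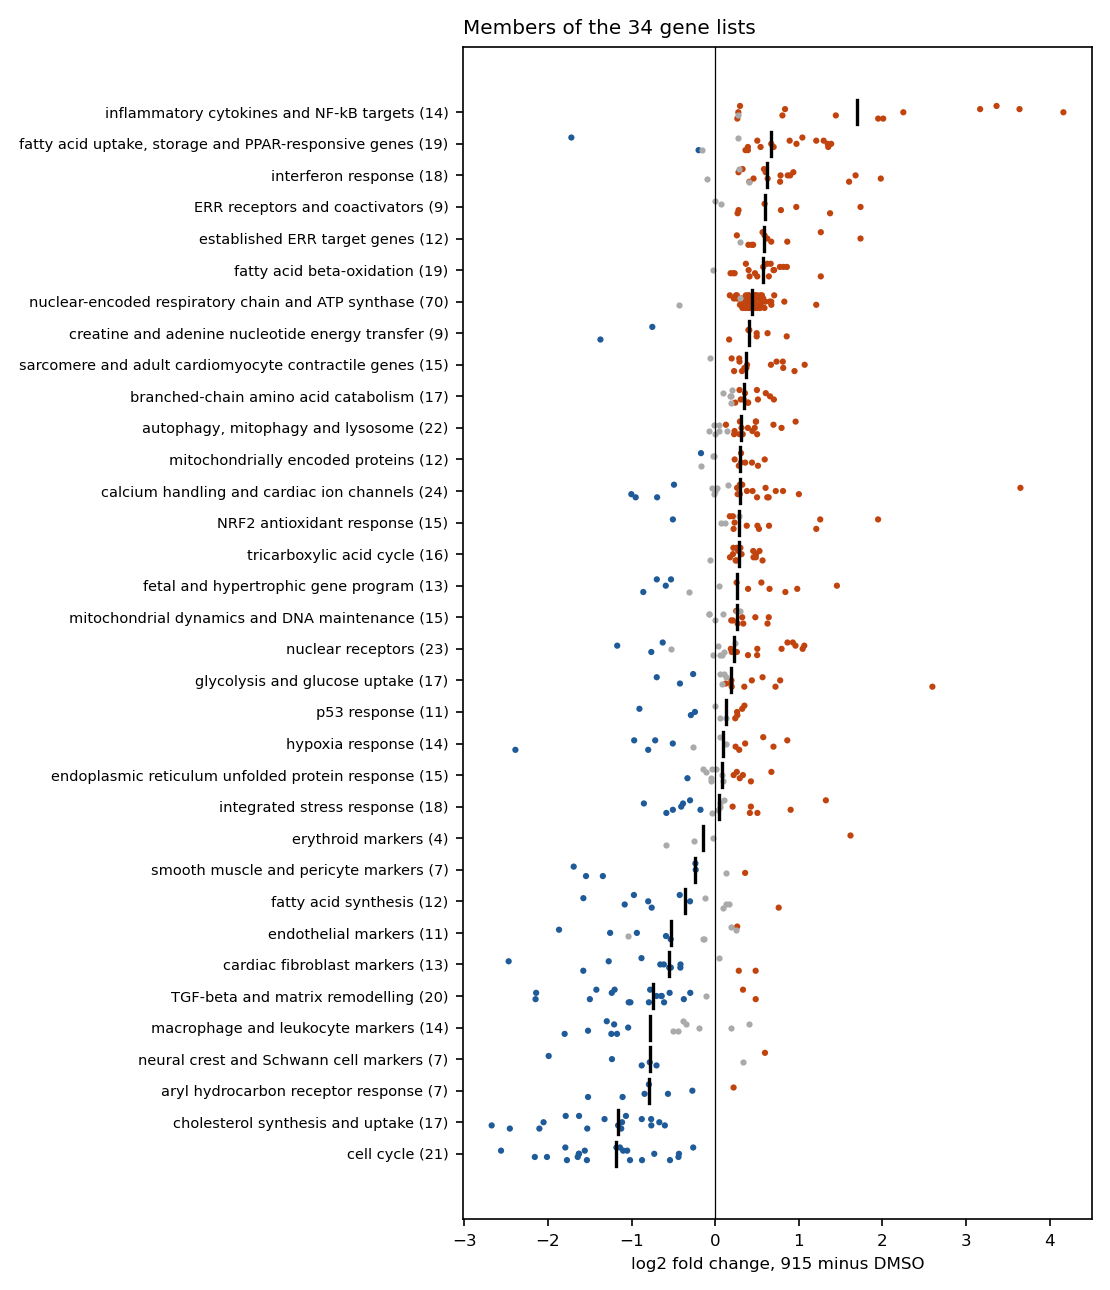
Log2 fold change (915 minus DMSO) of each measured member of the 34 gene lists, which are ordered by their median (black bar) with the number of tested members in brackets. Red and blue points passed an edgeR adjusted p of 0.05 and grey points did not. The inflammatory list lies highest, at a median of 1.70, and the cell cycle list lowest, at −1.18.

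Genes for other fuels and for energy transfer were also higher. Beside Slc2a4 (log2 fold change 2.60 ± 0.0665, edgeR adjusted p = 2.90e-12), the glycolytic genes Hk2 and Ldhb rose 1.71-fold and 1.65-fold. In the glycolysis and glucose uptake list 10 of 17 members were higher and 3 lower, and the median was 0.19 (camera adjusted p = 8.43e-03; adjusted p = 0.377 with an estimated correlation). Of 17 genes of branched-chain amino acid breakdown 12 were higher and 0 lower, or 13 and 0 adjusted over the list alone (median 0.34, camera adjusted p = 3.38e-05; adjusted p = 0.202 with an estimated correlation). Bckdha, Ivd and Aldh6a1 of that pathway rose 1.63-fold, 1.57-fold and 1.41-fold. Of 9 genes of creatine and adenine nucleotide energy transfer 7 were higher and 2 lower (median 0.41, camera adjusted p = 0.0183; adjusted p = 0.331 with an estimated correlation). The oxygen store gene Mb rose 1.81-fold and the adenine nucleotide carrier gene Slc25a5 1.54-fold, whereas Ckb, the brain-type creatine kinase, was 1.68-fold lower. Non-myocyte markers moved with these lists, at medians of −0.55 for fibroblasts, −0.24 for smooth muscle and −0.77 for macrophages.

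Contractile genes rose with the metabolic genes. Of 15 measured sarcomere genes 14 were higher and 0 lower, with a median of 0.37 (camera adjusted p = 2.60e-06; adjusted p = 0.245 with an estimated correlation). Cardiac troponin I, Tnni3, rose 2.10-fold (log2 fold change 1.07 ± 0.0605, 976 ± 86.6 and 1981 ± 16.8 CPM), and Myl3 and Tnnc1 rose 1.93-fold and 1.75-fold. The adult rodent myosin heavy chain gene Myh6 increased more than its fetal counterpart Myh7, by 0.81 ± 0.0614 against 0.39 ± 0.0468 on the log2 scale, and the change of their ratio passed its own test (0.43 ± 0.0796, limma adjusted p = 8.84e-05 over 15 gene pairs chosen after the data were seen). The natriuretic peptide genes, known markers of cardiac stretch and hypertrophy, also rose: Nppb 2.74-fold from 148 ± 9.31 to 393 ± 32.4 CPM and Nppa 1.47-fold from 970 ± 62.9 to 1375 ± 113 CPM. The fetal and hypertrophic list as a whole was split, with 7 of 13 members higher, such as Rcan1 and Fhl1 at 1.97-fold and 1.79-fold, and 4 lower, or 5 adjusted over the list alone (camera adjusted p = 0.136; adjusted p = 0.507 with an estimated correlation). In fry this list was called higher (fry adjusted p = 1.50e-03). Among 24 genes of calcium handling and ion channels 15 were higher and 4 lower (median 0.29, camera adjusted p = 2.72e-03; adjusted p = 0.282 with an estimated correlation). The gap junction gene Gja1 and the calcium pump gene Atp2a2 rose 2.00-fold and 1.75-fold, and the pacemaker channel gene Hcn4 fell 2.00-fold. Fibroblast, smooth muscle and macrophage markers were lower in these libraries, with list medians of −0.55, −0.24 and −0.77.

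**Figure D3:**
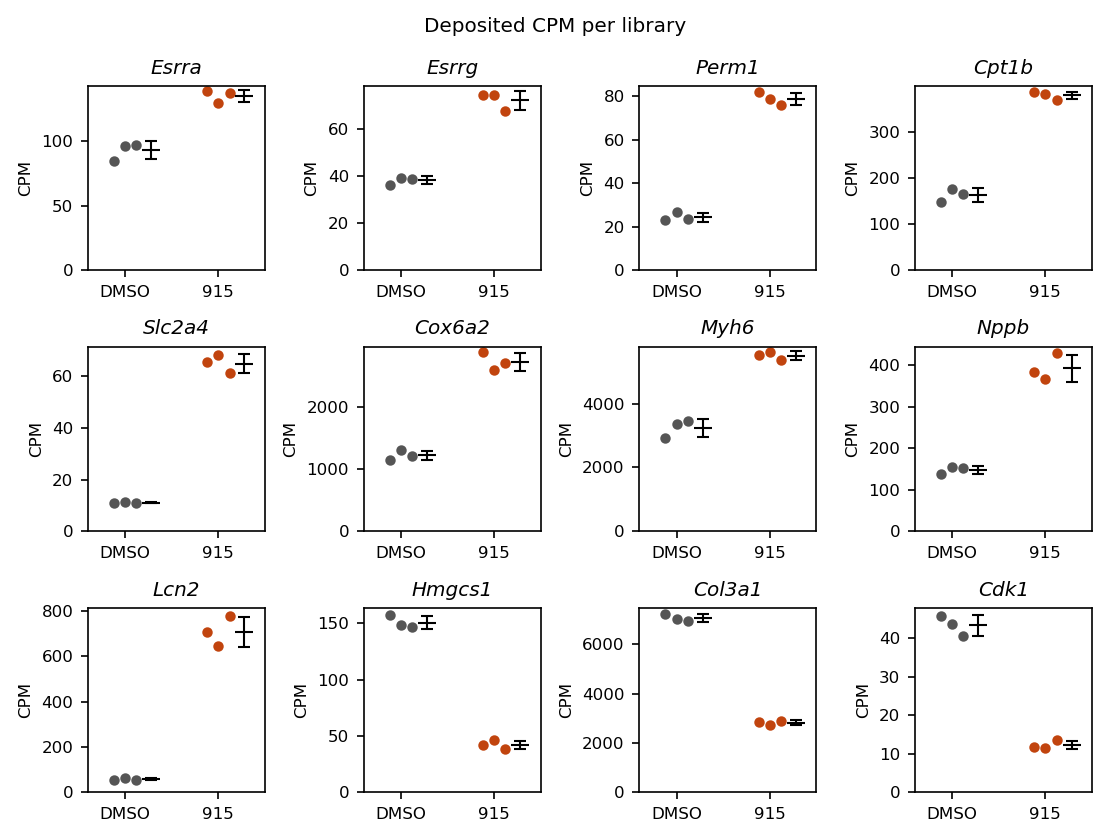
Deposited CPM of 12 genes in each of the 6 libraries (points, 3 DMSO and 3 with 915), with the group mean and SD beside them and every vertical axis starting at 0. For each of these genes the 3 libraries with 915 lie on one side of the 3 with DMSO, as for Esrra with means of 92.8 and 135 CPM.

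Genes of cell division fell as a group. All 21 measured cell cycle genes were lower, with a median log2 fold change of −1.18, and this was the list whose call remained with an estimated correlation (camera adjusted p = 3.51e-12; adjusted p = 0.0471 with an estimated correlation). The cyclin gene Ccna2, the mitotic kinase gene Cdk1 and the mitotic activator gene Cdc20 were 4.03-fold, 3.42-fold and 3.09-fold lower, and the kinetochore gene Cenpf 5.90-fold lower. The log2 fold change of Cdk1 was −1.77 ± 0.0795 (edgeR adjusted p = 4.22e-10). Markers of fibroblasts, smooth muscle and macrophages, cells that can divide in culture, fell in the same libraries, with list medians of −0.55, −0.24 and −0.77. Genes of the p53 response did not shift as a list in camera (adjusted p = 0.254, or 0.377 with an estimated correlation), with 5 of 11 higher and 3 lower. In fry, which does not compare them with other genes, the list was called higher (fry adjusted p = 2.82e-03). Cdkn1a, an inhibitor of cyclin-dependent kinases, rose 1.20-fold, Mdm2 1.27-fold and Gadd45a 1.25-fold.

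Sterol genes fell to a similar extent. All 17 measured genes of cholesterol synthesis and uptake were lower, with a median of −1.16 (camera adjusted p = 4.12e-12; adjusted p = 0.0822 with an estimated correlation). The synthesis gene Hmgcs1 was 3.45-fold lower, from 151 ± 6.08 to 42.2 ± 3.68 CPM (−1.79 ± 0.0628, edgeR adjusted p = 4.22e-11). The fibroblast, smooth muscle and macrophage marker lists were also lower, at medians of −0.55, −0.24 and −0.77. Of 12 genes of fatty acid synthesis 7 were lower and 1 higher (median −0.36, camera adjusted p = 0.0296; adjusted p = 0.377 with an estimated correlation). Acly, which makes cytosolic acetyl-CoA, and the desaturase gene Fads2 fell 1.96-fold and 2.12-fold. The higher member was Acacb, at 1.69-fold, whose product makes the malonyl-CoA that restrains fatty acid entry into mitochondria.

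Inflammatory genes had the highest median change of the 34 lists. Of 14 measured cytokine and NF-kB target genes 13 were higher and 0 lower, or 14 and 0 adjusted over the list alone, and the median log2 fold change was 1.70 (camera adjusted p = 2.93e-08; adjusted p = 0.204 with an estimated correlation). The iron-binding lipocalin gene Lcn2 went from 58.8 ± 5.15 to 708 ± 66.2 CPM, 12.5-fold (3.64 ± 0.0802, edgeR adjusted p = 9.44e-13). The chemokine genes Cxcl1 and Ccl2 reached 68.1 ± 9.01 and 155 ± 19.2 CPM with 915. Macrophage and leukocyte markers were lower in the same libraries, with a list median of −0.77. Interferon response genes were higher in 15 of 18 cases and lower in 0 (median 0.62, camera adjusted p = 7.69e-04; adjusted p = 0.462 with an estimated correlation; fry adjusted p = 0.0599), with Cxcl10, Ifit3 and Rsad2 at 3.94-fold, 3.20-fold and 3.03-fold. DMSO library 2 stood apart in these genes, with a mean log2 level 0.47 above the DMSO mean where DMSO libraries 1 and 3 were at −0.25 and −0.23 and the 915 libraries at 0.92, 0.50 and 0.91. Without DMSO library 2 the median was 0.99 and 17 of 18 genes were higher, whereas 11 were higher without DMSO library 1 (median 0.51), DMSO library 3 (0.55) or 915 library 3 (0.55), 12 without 915 library 1 and 15 without 915 library 2.

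Matrix genes and most markers of cells other than myocytes were lower. The TGF-beta and matrix remodelling list had 17 of 20 members lower and 2 higher, with a median of −0.74 (camera adjusted p = 1.37e-07; adjusted p = 0.245 with an estimated correlation). Elastin, Eln, fell 4.43-fold from 1918 ± 129 to 418 ± 20.2 CPM, and Col5a1 and Fbn1 fell 2.68-fold and 2.36-fold. Among 13 measured fibroblast markers 10 were lower and 2 higher (median −0.55, camera adjusted p = 1.86e-03; adjusted p = 0.223 with an estimated correlation). The surface marker Thy1 and the fibrillar collagens Col3a1 and Col1a1 fell 5.54-fold, 2.42-fold and 1.84-fold, while Dcn and Pdgfra, named here after their values were seen, rose 1.4-fold and 1.22-fold. Of 7 smooth muscle and pericyte markers 5 were lower and 1 higher, with Tagln, Cnn1 and Mylk at 3.23-fold, 2.92-fold and 2.54-fold lower (camera adjusted p = 0.0118; adjusted p = 0.255 with an estimated correlation). Of 14 macrophage and leukocyte markers 7 were lower and 0 higher (camera adjusted p = 1.87e-03; adjusted p = 0.255 with an estimated correlation), with Lyz2, Mrc1 and Csf1r at 2.06-fold, 2.31-fold and 2.46-fold lower. Endothelial markers were lower in 5 of 11 cases and higher in 1, or 6 lower adjusted over the list alone (camera adjusted p = 0.174; adjusted p = 0.308 with an estimated correlation). Fry called the endothelial list lower (fry adjusted p = 6.76e-04). Esam, Tek and Flt1 of that list fell 2.39-fold, 1.5-fold and 1.45-fold, while 3 of the 11 were lower without DMSO library 3 and 2 were higher without DMSO library 2. Neural crest and Schwann cell markers were lower in 5 of 7 cases and higher in 1 (camera adjusted p = 0.0873; adjusted p = 0.255 with an estimated correlation), with Sox10, Mbp and S100b at 1.84-fold, 1.72-fold and 1.63-fold lower. Fry called the neural crest list lower too (fry adjusted p = 5.63e-04). Of 4 erythroid markers 1 passed, Hba-a2 at 3.06-fold higher and 1.04 ± 0.382 against 3.11 ± 0.930 CPM, a globin gene that the table counts under more than 1 identifier, so its value is uncertain (list median −0.14, mean 0.18 and camera direction upwards, camera adjusted p = 0.859; adjusted p = 0.902 with an estimated correlation). Without DMSO library 2 the erythroid median was 0.11 over 4 markers, and without DMSO library 3 it was −0.32 over 5 markers, with 1 lower. It was −0.30 without 915 library 1 and −0.29 without 915 library 2, also over 5 markers. Where 5 were tested, the filter for low counts let in another marker, so these medians cover a different set.

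Stress and sensor pathways moved in different directions, in libraries where the fibroblast, smooth muscle and macrophage lists had medians of −0.55, −0.24 and −0.77. Of 15 genes of the NRF2 antioxidant response 11 were higher and 1 lower, or 12 and 1 adjusted over the list alone (median 0.29, camera adjusted p = 5.25e-05; adjusted p = 0.255 with an estimated correlation). Heme oxygenase, Hmox1, rose 3.86-fold from 120 ± 7.03 to 448 ± 33.5 CPM, and Srxn1 and Osgin1 rose 2.39-fold and 2.31-fold. Of 22 autophagy, mitophagy and lysosome genes 16 were higher and 0 lower (median 0.30, camera adjusted p = 1.62e-05; adjusted p = 0.244 with an estimated correlation), with the autophagy receptor gene Sqstm1 and the mitophagy genes Pink1 and Bnip3 at 1.95-fold, 1.73-fold and 1.62-fold. The aryl hydrocarbon receptor list had 6 of 7 members lower and 1 higher (median −0.79, camera adjusted p = 5.05e-03; adjusted p = 0.204 with an estimated correlation). Its enzyme genes Aldh3a1, Cyp1a1 and Cyp1b1 fell 2.87-fold, 2.15-fold and 1.48-fold. The integrated stress response did not shift as a list (camera adjusted p = 0.744; adjusted p = 0.909 with an estimated correlation): 6 of 18 members were higher, such as Gdf15 and Ddit3 at 2.5-fold and 1.87-fold, and 7 lower, such as the serine synthesis gene Psat1 at 1.81-fold. The unfolded protein response did not shift in camera either (adjusted p = 0.164, or 0.521 with an estimated correlation), although fry called the list higher (fry adjusted p = 0.0137). Of its 15 members 6 were higher and 1 lower, or 6 and 2 adjusted over the list alone. Without DMSO library 2 the lower members numbered 3. Dnajb9 and Herpud1 rose 1.59-fold and 1.26-fold and Pdia4 fell 1.26-fold. Hypoxia response genes went both ways, 6 of 14 higher and 5 lower, with a positive median of 0.09 and a negative mean of −0.18. Camera did not call the list (adjusted p = 0.967, and 0.967 with an estimated correlation), whereas fry called it lower (fry adjusted p = 6.13e-04). Car9 and Ndrg1 of that list fell 5.24-fold and 1.96-fold, and Vegfa rose 1.82-fold. Among 23 nuclear receptors 13 were higher and 3 lower (median 0.23, camera adjusted p = 4.09e-03; adjusted p = 0.202 with an estimated correlation), with Nr0b2 and Nr4a1 at 2.06-fold and 1.94-fold higher and Nr2f2 at 2.25-fold lower.

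Among genes averaging at least 5 CPM whose 915 libraries all lay on the same side of all DMSO libraries, the highest fold changes belonged to Slpi, a protease inhibitor (12.5-fold, from 1.09 ± 0.326 to 13.2 ± 0.926 CPM), Lcn2 and Cxcl1. They were followed by Pla2g2a, a secreted phospholipase (7.28-fold), Gnb3, a G protein subunit (6.83-fold), Trh, the thyrotropin-releasing hormone gene (6.73-fold), the cytokine receptor gene Csf2rb (6.24-fold) and the calcium-binding protein gene Pvalb (6.11-fold). The embryonic myosin heavy chain gene Myh3 fell most, 9.0-fold from 21.3 ± 1.96 to 2.29 ± 0.239 CPM (−3.17 ± 0.118, edgeR adjusted p = 7.10e-11). Other genes among the lowest were the natriuretic peptide clearance receptor gene Npr3 (6.25-fold lower), the anchoring protein gene Akap5 (5.92-fold lower), Cenpf, the growth factor binding protein gene Igfbp2 (5.61-fold lower) and Thy1. Mir675 was 6.54-fold lower, but this microRNA lies within the H19 transcript and the reads of both cannot be told apart in the table.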

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

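The scaling by library totals alone and the use of the authors' totals were chosen after seeing the data. All 116 named genes kept their direction and their side of the threshold in all 2085 values, each of 1 gene under 1 alternative. Of these values 696 had 1 library left out. Most of the genes had been named for a small p or a large fold change, which makes such stability likely. The number of genes changed stayed within 1.5 times 7096 under each alternative, with a range of 6071 to 7047 when each library was left out in turn. The number changed at least 2-fold, 1236, ranged from 1180 to 1301 with a library left out. It was 643 (117 higher and 526 lower) with limma-trend on log2(CPM + 1), where the added constant shrinks the folds of low genes by construction. Library totals alone gave 2808 higher and 4285 lower genes, 39.6% higher against 48.8%. Of 577 list values 545 held, 26 lost their call, 5 gained one and 1 turned its direction. With an estimated inter-gene correlation the number of lists shifted was 1 instead of 26. The adjusted p was then 0.233 for established ERR targets, 0.255 for fatty acid oxidation, 0.261 for the tricarboxylic acid cycle and 0.263 for the respiratory chain. Some lists whose estimated correlation was below the preset 0.01 lost their call too. The camera adjusted p of the aryl hydrocarbon receptor list (estimated correlation −0.0646) went from 5.05e-03 to 0.204. That of the nuclear receptor list (−0.0370) went from 4.09e-03 to 0.202. Higher correlations among members therefore do not account for the loss in these 2 lists. The cell cycle list, whose estimated correlation of 0.00186 was also below the preset, went from a camera adjusted p of 3.51e-12 to 0.0471. With an estimated correlation, camera takes its degrees of freedom from the 6 libraries and not from the genes, which by itself raises p-values. How much of the rise came from this in each list was not tested. The hypoxia list, without a call in camera, was lower in fry (adjusted p = 0.000613), with a mean of −0.18 and a median of 0.09. Why the 2 tests differed there was not tested. The 204 list values with 1 library left out all held. The difference in mitochondrial share ranged from 1.26 to 1.85 percentage points.

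With the replicate number as a replicate block, 6193 genes were called, 2996 higher and 3197 lower, 6172 of them shared with the fit without it, and no call of a list or named gene changed. Deviations of same-numbered libraries from their group means correlated across genes at −0.03, −0.11 and −0.09. This gave no sign that the numbers pair the libraries, but a pairing that is weak or limited to some genes could look the same. Depth limits what can be said of genes near 0.0917 CPM, the level of 3 counts in the shallowest library.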

Other observations

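Gene families taken by symbol, and the isoform pairs below, were chosen after the data were seen. Of 71 measured mitochondrial ribosomal protein genes 55 were higher with 915 and 0 lower (median log2 fold change 0.30), whereas of 85 cytosolic ribosomal protein genes 4 were higher and 31 lower (median −0.15). Mitochondrial import genes of the Timm and Tomm families were higher in 16 of 23 cases and lower in 0 (median 0.31), and proteasome subunit genes were higher in 26 of 35 and lower in 0 (median 0.22). Of 31 heat shock protein genes 17 were higher and 5 lower (median 0.20). Collagen genes were lower in 29 of 37 cases and higher in 1 (median −0.85), and kinesin genes, the motors used in transport and mitosis, were lower in 18 of 36 and higher in 1 (median −0.38). Of 4 metallothionein genes 3 were higher, and the family median of 1.85 was close to that of Mt2A, a metal-binding stress protein gene that went from 188 ± 16.6 to 658 ± 13.2 CPM (edgeR adjusted p = 2.40e-11).

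Several pairs of genes encode a form that prevails in the neonatal heart and one that prevails in the adult heart. A wider shift from neonatal to adult isoforms is a hypothesis of this section, with pairs and test chosen after the data were seen. In a limma test of the log2 ratio, the adult member gained on the neonatal one in 12 of 15 pairs and lost in 3, with a median change of 0.69. The gain was 2.47 ± 0.0807 (SE) for Slc2a4 over Slc2a1, 1.6 ± 0.0737 for Tnni3 over Tnni1, 1.54 ± 0.0629 for Myl3 over Myl4, 1.25 ± 0.0617 for Ckm over Ckb and 1.06 ± 0.0683 for Cpt1b over Cpt1a. Pairs in which the neonatal member gained included Eno3 over Eno1 (−0.50) and Slc25a4 over Slc25a5 (−0.23). Because some of these genes were already known to have changed when the pairs were chosen, the 12 pairs are a description. They do not test the hypothesis, which stays open. So does a change in cell makeup for pairs with forms such as Slc2a1, which other cells also use. In pairs of contractile genes, a lower share of non-myocytes alone would leave the ratio unchanged if no other cell expressed either member. The adult member gained in all of these: Tnni3 over Tnni1, Myl3 over Myl4, Myl2 over Myl7 (1.52 ± 0.0759) and Myh6 over Myh7 (0.43 ± 0.0796). They argue against that lower share as the whole cause for their genes. A change between kinds of myocytes was not tested.

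The tests of cell makeup and of leukocytes below were chosen after their results were seen, and the others before. Fatty acid oxidation and respiratory chain genes rose while most markers of fibroblasts, smooth muscle and macrophages fell. The fibroblast markers did not fall alike, as they would with a lower share of fibroblasts alone if no other cell expressed them. Of 13 markers 2 were higher (Dcn and Pdgfra), while Postn stayed at 1606 and 1597 CPM (log2 fold change 0.04, edgeR adjusted p = 0.473). These values were known when the test was chosen and other cells can express the markers. They do not settle whether a lower share of fibroblasts was the whole cause. A lower share of all non-myocytes remains open for the metabolic genes, because it would raise them by no more than contractile genes, and their medians exceeded the sarcomere median by 0.20 (fatty acid oxidation, one-sided permutation p = 0.219) and 0.07 (respiratory chain, p = 0.0501), with contractile genes themselves possibly changed by 915. The axis on which DMSO library 2 differed from the other DMSO libraries was considered as a source of the respiratory chain shift. Of 10000 random lists matched on that deviation and on expression, 0% reached its median of 0.44. The matched lists had a median of 0.21 of their own, so genes with a like deviation typically rose, but by less. The random lists take genes as independent, while the respiratory chain genes had an estimated correlation of 0.613. The comparison therefore does not decide whether that axis was the whole source. For these metabolic genes, an action of 915 within the myocytes stays open as the biological explanation. It was not separated from a change in cell makeup. Cell makeup was not tested for the lower cell cycle genes. Contractile genes did not move alike. Of the sarcomere list 14 of 15 were higher, as was the neonatal form Myh7 (log2 fold change 0.39). The neonatal forms Tnni1, Myl4 and Myl7 were lower (−0.53, −0.59 and −0.86). A lower share of non-myocytes alone would raise all of them if no other cell expressed them. These values argue against it as the whole cause for these contractile genes.

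Inflammatory genes rose, with Lcn2 at 12.5-fold and Cxcl1 at 8.98-fold. More leukocytes in the treated cultures would raise leukocyte markers, but the median log2 fold change of that list was −0.77, with 7 of 14 members lower and 0 higher. A single unusual library is also argued against, since at least 13 of the 14 inflammatory genes were higher whichever library was left out. Which of the remaining cells made these transcripts, and whether they follow from the receptors or from a general stress of the cultures, was not tested.

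Cholesterol synthesis genes fell together. A lower share of non-myocytes would lower them by no more than the markers of those cells. Their median of −1.16 lay below that of the fibroblast list by 0.61 (one-sided permutation p = 0.0141), and the macrophage list had a median of −0.77. Single markers fell further, such as Thy1 (−2.47) and Tagln (−1.69), and the permutation takes the genes of a list as independent. The comparison therefore does not decide whether a lower share of non-myocytes was the whole cause. A hypothesis is that the treated cells held more sterol, which would raise targets of the liver X receptors, the sterol sensors. Of 5 such targets 4 were higher (Abcg1 by 1.00, Abca1 by 0.35, Lpcat3 by 0.32 and Pltp by 0.31 on the log2 scale) and Mylip did not pass (0.00, edgeR adjusted p = 0.992), for a median of 0.32. The 4 higher targets go with more sterol, but direct action on them by 915 or by another nuclear receptor stays open. Sterol was not measured. Scd, Fasn and Srebf1, further known targets named after their values were seen, were not called higher. Scd and Fasn were lower (−1.58 and −0.42, edgeR adjusted p = 1.77e-07 and 4.24e-06), and Srebf1 did not pass (0.13, edgeR adjusted p = 0.0895).

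The 6 libraries can be split into 3 and 3 in 10 ways, too few for a share under 0.05. The real grouping gave 7096 genes, 1236 genes changed at least 2-fold and 26 lists. The highest of the other splits gave 0, 0 and 17, so that in each case 1 split, the real one, gave as many. Each other split placed treated and control libraries in both groups, so a difference between them widened the spread within groups. Few called genes were therefore likely there, and these splits do not decide how many calls arise by chance. For the lists, camera with the preset correlation still called 7 to 17 in splits that kept only part of the treatment contrast.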
